A study of Drosophila melanogaster with 4 samples.

How the data were processed

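Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on Drosophila melanogaster embryos aged 0 to 12 h of a y; cn bw sp stock. The antibody was a crude polyclonal guinea pig serum against Scute. Per the labels, the series holds 4 libraries: 2 scute ChIP libraries and 2 libraries of input DNA, numbered 1 and 2 in each group. Input DNA is sheared chromatin taken before immunoprecipitation and serves as the background. Nothing in the labels says whether the replicates were separate embryo collections.

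Per the file headers, peaks were placed on FlyBase release 5 of the genome (BDGP5 in the submitters' processing notes). Per the submitters' processing notes, CASAVA (versions 1.7.0.2 and 1.7.0.3), BWA and MACS2 were used. The versions of BWA and MACS2, the read filters, the peak threshold, the pooling of replicates and the use of the input in peak calling are not given in the sources used here. The processed data consist of 1 list of peaks for the whole series, each with a start, an end and a score and with no value per library. Read depth per library is therefore unknown, and no error between replicates could be computed. The number of peaks limits the precision, and intervals below cover counting or placement along the chromosome alone.

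The deposited score is not named in the file and was read here as −log10 of a p-value. This reading came from the values: the −log10 upper tail of a Poisson distribution was computed for every whole-number pileup at background means from 5 to 150. The mean that gave the most scores within 0.01 was then refined by least squares. At a mean of 50.145 overlapping fragments, 74.1% of the 2136 scores (1582) matched to within 0.01, up to the highest score in the list. Other means matched a median of 6.46% and at most 28.0%. A matched score gives the pileup at the peak, with an uncertainty of 1 fragment in how the tail is counted, and its fold over that background. MACS compares each region with the larger of a genome-wide and a local background. A score that matched can thus come from the genome-wide background. One that did not (554 peaks) can come from a higher local background or from a small numerical deviation beyond the tolerance. The latter may hold for some: 100 of the 554 lay within 0.02 of a computed value, 54 of them with a score of 8.52 where 8.53 was computed. Rounding to 2 decimals alone does not give that difference, and its source is unknown. Within 0.02, the share matched was 78.7%, against a median of 13.4% at other means. Pileups and folds of unmatched peaks were not computed. Fragment length is not given in the sources used here, so the background of 50.145 was not converted into a number of reads.

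Peaks per sequence were compared with their expectation by length through 100000 random draws of all peaks over the 8 sequences, two-sided, with Benjamini-Hochberg adjustment. No genome of release 5 was used here, so the highest peak end on each sequence stood for its length. Confidence intervals (95%) of densities came from 10000 bootstrap draws of 1 Mb windows. Clustering was measured as the share of peaks with another midpoint at most 10 kb away on the same sequence. It was compared with 1000 random placements between the first and last peak of each sequence, one-sided. Chains of peaks with successive midpoints at most 10 kb apart were counted as loci. Correlations across peaks and differences in median score had permutation p-values (100000 permutations, two-sided). Shares have exact Clopper-Pearson intervals or Fisher's exact test. Peaks of 1 list are not independent replicates, so each p-value describes this list and not the spread between embryo collections.

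Before the data were examined, the comparisons, the alternatives and the rule for naming peaks were fixed. Without an annotation of the file's release, that rule names the 15 highest-scoring peaks, the highest-scoring peak on each sequence, the 3 widest peaks and the 5 loci with the most peaks. The planned annotation of peaks, 20 fixed gene lists and the motif comparisons were not run. The gene table at hand is of release 6, and coordinates were not converted between releases, so peaks are named by position and not by gene. Alternatives fixed then were the highest-scoring 50% and 25% of peaks, merging of peaks within 500 bp, other lengths, sets of sequences and distances, and another random placement. The reading of the score, the shares matched, the 1 Mb windows as units and the Fisher tests were added after the data were seen.

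The background fit and the tests were run on simulated data, in part after the results were seen. A simulated background of 37.4 was recovered as 37.401, and 100% of the simulated pileups at that background were recovered exactly. Of 20 simulated lists placed by length, 1 gave a call on any sequence, and the X was called in all 20 lists with the X at 0.5 of its share. With 30% of peaks planted beside another, the clustering test gave a permutation p = 0.0050 over the peaks on the main arms, and with random placement p = 0.71. A planted correlation of 0.5 was recovered as 0.51 (permutation p = 5.0e-04), and without one p = 0.21. These checks used fewer random draws than the tests themselves. The permutation p-values of 0.0050 for planted clustering and 5.0e-04 for the planted correlation are the smallest that those draws can give. A shift of 0.5 SD gave a permutation p of 0.0030 for the difference in medians, and no shift p = 0.17. The window permutation made a call in 0 of 20 sets with equal means and in all 20 with the X at 0.35. Over 200 simulated sets of X windows, 91.0% of the 95% density intervals held the true density, so these intervals are somewhat too narrow. The work used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.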

Results

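The data describe where ChIP with a serum against Scute gave peaks in Drosophila embryos collected over the first 12 h of development. Whether each peak reflects binding of Scute was not tested. Scute is a basic helix-loop-helix transcription factor of the achaete-scute complex. It promotes the formation of neural precursors, and as the product of an X-linked gene it also takes part in the signal by which X dose is read in sex determination. The 2 ChIP libraries and the 2 input libraries were represented by 1 list of 2136 peaks, with no value per library. The comparisons implied by the design were therefore made within that list, between chromosome arms and between positions along each arm.

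Scute peaks were narrow and mostly of modest height. The median peak was 312 bp wide (interquartile range 242 to 442 bp, range 201 to 3245 bp), and 46 of the 2136 peaks were wider than 1000 bp. Together the peaks covered 826 kb, and none overlapped another. The median score was 11.67 (−log10 p, interquartile range 9.74 to 15.13, range 6.07 to 139.55). Scores below 20 made up 87.4% of the list, and 26 peaks reached 50 or more. The 1582 peaks whose score matched the genome-wide background of 50.145 fragments had a median pileup of 106 fragments, which is 2.11-fold over that background (interquartile range 1.99 to 2.33, highest 6.30). The score rose with peak width across the list (Spearman's rho = 0.60, Pearson's r = 0.59, adjusted permutation p = 1.5e-05 for both, among 3 relations tested). Peaks are not independent replicates in these correlations. Score and width also come from the same pileup, so a rise of 1 with the other may be built in.

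**Figure D1:**
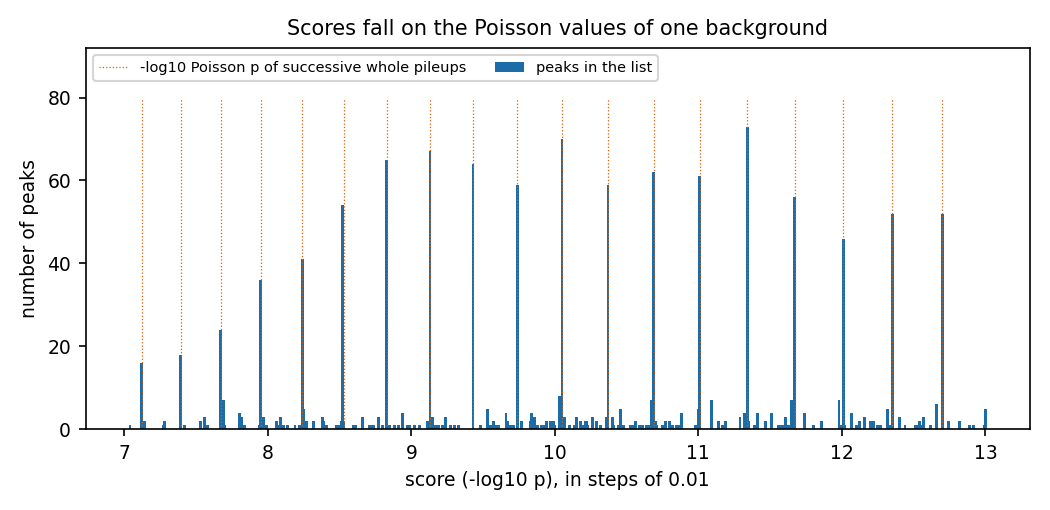
Number of peaks at each score between 7 and 13 (blue bars, score in −log10 p on the x axis), with the −log10 Poisson p of successive whole pileups at a background of 50.145 (dotted lines). The tall bars stand on the dotted lines, and 74.1% of all scores matched such a value within 0.01.

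The 3 highest-scoring peaks lay on 3R and 3L. The highest score, 139.55, belonged to a 912 bp peak on 3R from 8889530 to 8890441 (FlyBase release 5), where the pileup reached 316 fragments or 6.30-fold over background. It was followed by a peak of 1834 bp on 3L from 7905104 to 7906937 (score 124.57, 5.92-fold) and another on 3R from 11925152 to 11925984 (score 113.86, 5.64-fold). The fourth peak by score was on 2R from 15998517 to 15999060 (score 91.95, 5.05-fold). A neighbour on 2R from 15993883 to 15994288 held rank 9 with a score of 72.22. On 3R, peaks from 12759923 to 12760656 (score 76.84) and from 21867612 to 21868735 (score 57.72) were also among the 15 highest.

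The X carried 2 of the 15 highest-scoring peaks. These lay from 17720945 to 17721446 (score 75.51, 4.57-fold) and from 19531135 to 19532242 (score 67.69, 4.33-fold). On 2L, 3 peaks were in this group, from 6323898 to 6324593 (score 72.22), from 3152403 to 3153503 and from 4811206 to 4811972 (score 67.05 for both). The remaining 3 were neighbours on U, a sequence that joins unplaced scaffolds of the assembly. They lay from 2175356 to 2177712 (score 80.65), from 2169649 to 2171334 (score 58.32) and from 2172620 to 2175287 (score 57.72). The 3 widest peaks of the list were on U as well, the widest from 2178125 to 2181369 with 3245 bp and a score of 36.29. The highest peak on chromosome 4 lay from 1316195 to 1316943 (score 25.14, 2.79-fold). On Uextra, a second set of unplaced scaffolds, the highest lay from 4984973 to 4985322 (score 32.25, 3.09-fold).

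**Figure D2:**
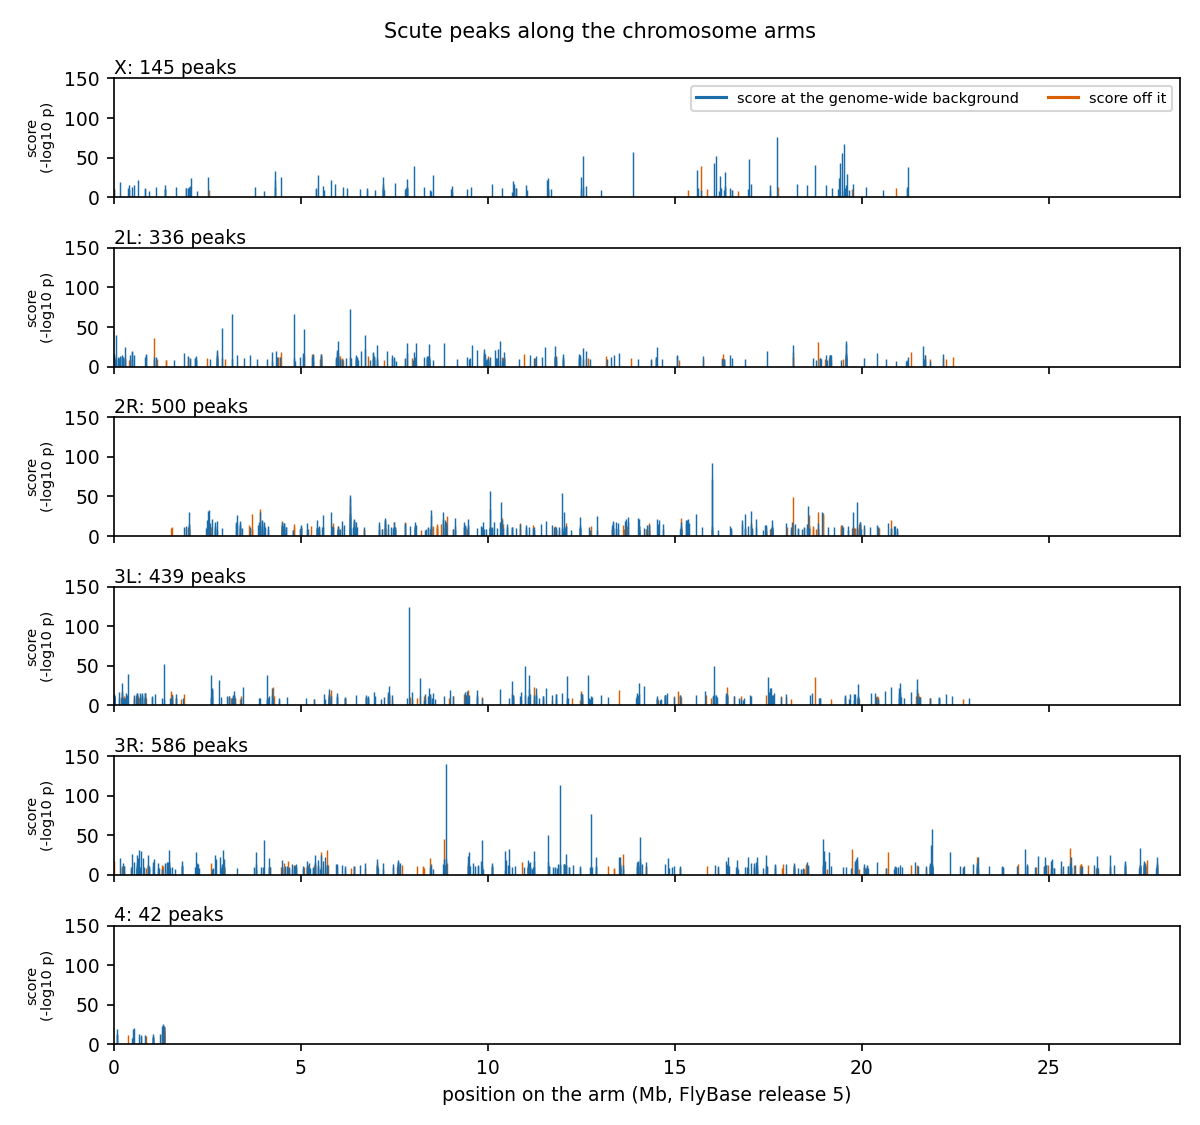
Score of each peak (−log10 p, y axis) against its position on arms X, 2L, 2R, 3L, 3R and 4 (Mb, x axis), in blue where the score matched the genome-wide background and in orange where it did not. The tallest line is the peak of score 139.55 on 3R, and the X shows 145 peaks.

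The X held far fewer scute peaks than its length would give over all 8 sequences, and 2R, 3L and 3R held more. The X had 145 peaks, or 6.83 per Mb (95% interval 5.05 to 8.76 over 1 Mb windows). The density was 15.0 per Mb on 2L (11.4 to 19.0), 23.9 on 2R (19.9 to 27.5), 19.2 on 3L (14.9 to 25.04) and 21.0 on 3R (17.5 to 24.5). The density on the X was thus 0.35 times that of the 4 large autosome arms together (95% interval 0.25 to 0.46). Against a placement by length over all 8 sequences, the X had 0.49 times the expected number. The ratio was 1.72 for 2R, 1.38 for 3L and 1.51 for 3R (adjusted permutation p = 2.3e-05 for each of these 4, from the smallest p of 2e-05 that the draws can give). The 336 peaks on 2L were not shown to differ from their expectation (ratio 1.08, adjusted permutation p = 0.14). With the 5 main arms alone, the sparse unplaced scaffolds no longer lowered the expectation, though the X still did. The ratio was then 1.37 for 2R, 1.10 for 3L (adjusted permutation p = 0.024), 1.21 for 3R and 0.39 for the X. For 2L it fell to 0.86 (adjusted permutation p = 0.0034). The 4 large autosome arms together had 19.8 peaks per Mb. Beside that density 2R and 3R lay above and 2L and 3L below, so 3L held no excess over the other autosome arms. The draws take peaks as independent although they were grouped, so their p-values may be too small, above all for 2L and 3L. Only the X was also compared with 1 Mb windows as units. The excess on 3L over all 8 sequences was not detected in the highest-scoring 25% (ratio 1.08, adjusted permutation p = 0.51).

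The difference between the X and the autosomes held with 1 Mb windows as units. X windows had 6.76 ± 4.49 peaks per Mb (SD, n = 21 windows) and windows of the large autosome arms 19.8 ± 10.8 (SD, n = 94 windows; permutation p = 1e-05, the smallest that the permutations can give). The density ratio was 0.39 (95% interval 0.29 to 0.50) in the highest-scoring 50% of the list and 0.50 (0.33 to 0.70) in the highest-scoring 25%. In those 534 peaks the X still had 0.65 times its expected number (adjusted permutation p = 0.0017). Among the 100 highest-scoring peaks the ratio was 0.97 with a wide interval (0.43 to 1.73, 16 X peaks). The X supplied 10.1% of main-arm peaks in the highest-scoring 25% of the list and 6.34% of the others (48 of 476 and 97 of 1530, Fisher's exact test, two-sided, p = 0.0082). The median score was 12.01 on the X and 11.34 on the large autosome arms (adjusted permutation p = 0.14), while the 90th percentile was 32.5 on the X and 20.8 on those arms. Within the highest-scoring 50% and 25% the X median was higher by 1.89 and 5.395 (adjusted permutation p = 0.010 and 0.0011). Scores of X and autosomal peaks may not be on the same footing. The genome-wide background was matched by 92.4% of X peaks and by 74.3% of those on the large autosome arms. A higher local background would lower the score at a given pileup.

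Chromosome 4, the small and largely heterochromatin-like autosome, had 42 peaks or 31.1 per Mb, 2.24 times its expectation over all sequences (adjusted permutation p = 2.3e-05). The sparse X, U and Uextra lowered that expectation. The large autosome arms together had 19.8 peaks per Mb, so the excess of chromosome 4 over them was smaller. That smaller excess was not tested. Of the 42 peaks on chromosome 4, 17 lay in the last 36.9 kb of its peaks, from 1314939 to 1351845. The other 25 lay at lower coordinates and were not evenly spread, with a group of them just below that stretch. Without that stretch and the runs at the low-coordinate ends of 2L and 3L, the ratio for chromosome 4 was 1.36 (adjusted permutation p = 0.18). The group just below the stretch was kept in this ratio. The sparse X, U and Uextra again lowered the expectation, so the 1.36 does not show an excess over the large autosome arms. U had 35 peaks and Uextra 53, which is 0.26 and 0.14 times their expectation (adjusted permutation p = 2.3e-05 for both). Among the 100 highest-scoring peaks, U was above its expectation (ratio 1.57, adjusted permutation p = 0.52) and chromosome 4 held 0 peaks (adjusted permutation p = 0.83), neither past the threshold. The share of peaks that matched the genome-wide background within 0.01 was 92.4% on the X (exact interval 86.8 to 96.2) and 74.3% on the large autosome arms (72.2 to 76.2). It was 52.4% on chromosome 4 (36.4 to 68.0), 57.1% on U (39.4 to 73.7) and 45.3% on Uextra (31.6 to 59.6). Within 0.02 the shares were 95.2% on the X, 79.2% on the large autosome arms, 54.8% on chromosome 4, 62.9% on U and 47.2% on Uextra.

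**Figure D3:**
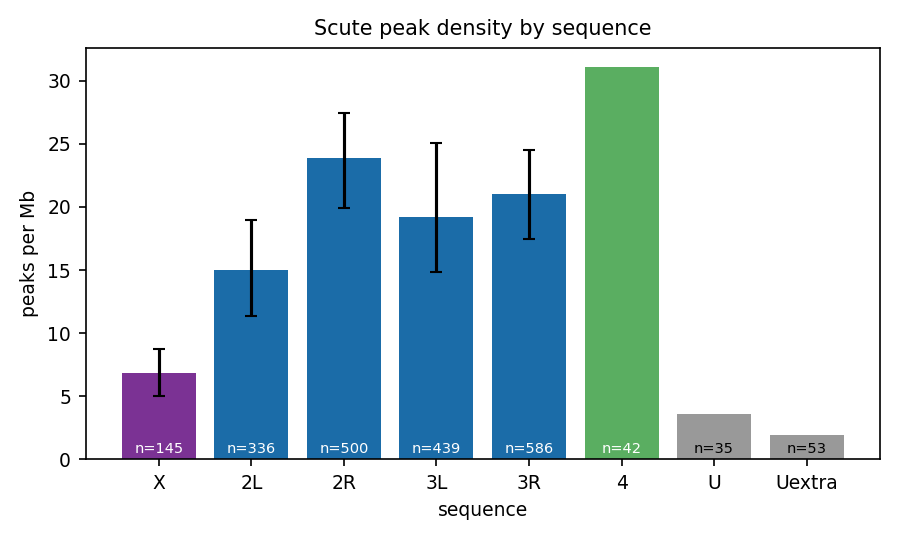
Peaks per Mb (y axis) on each sequence (x axis), with the number of peaks in each bar and 95% bootstrap intervals over 1 Mb windows for the X and the large autosome arms. The X stands at 6.83 per Mb, below all 4 large autosome arms.

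Scute peaks were grouped along the chromosomes. Of the 2136 peaks, 1506 (70.5%) had another peak within 10 kb, against 31.4% ± 1.27 (SD over 1000 random placements; permutation p = 0.0010, the smallest that they can give). The median distance to the nearest peak was 2.40 kb, and 18.7 kb under random placement. The share exceeded random placement on every one of the 8 sequences (adjusted permutation p = 0.0010 for each). It ranged from 22.6% on Uextra and 45.5% on the X to 79.0% on 2R, 83.3% on chromosome 4 and 88.6% on U. U and Uextra are made of unplaced scaffolds, so distances between their peaks need not be distances along a chromosome. With the main arms alone, a setting chosen after seeing the data, the share was 71.2% against 32.3% under random placement. The peaks formed 1066 loci, of which 630 were single peaks. The 83 loci with 5 or more peaks held 613 peaks, or 28.7% of the list.

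The locus with the most peaks was the low-coordinate end of 3L, with 21 peaks between 421 and 18763 and scores no higher than 14.47. The run on U from 2151318 to 2184107 held 17 peaks with a median score of 34.97, and the run on chromosome 4 from 1314939 to 1351845 also held 17, with a median of 15.91. On 3R, 15 peaks lay between 2898370 and 2953432, with the highest score of 31.26 from 2912755 to 2914384. A further 14 peaks on 3R lay between 21847755 and 21881014. That locus had a median score of 10.69 and contained one of the 15 highest-scoring peaks of the list.

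**Figure D4:**
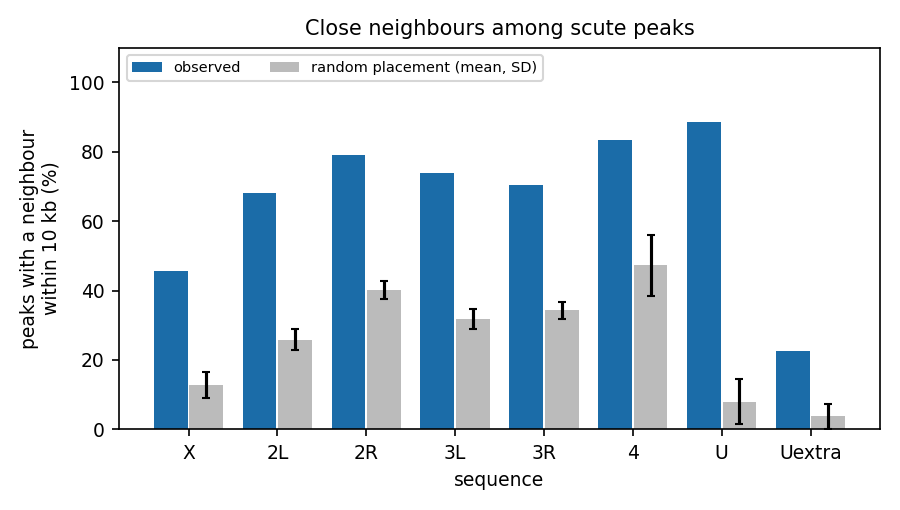
Percent of peaks with another peak within 10 kb (y axis) on each sequence (x axis), observed (blue) and over 1000 random placements (grey, mean with SD). The observed share lies above the random one on all 8 sequences, from 22.6% on Uextra to 88.6% on U.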

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

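Of the 110 values computed under alternative settings, 82 kept their direction and their side of the threshold or, without a test, stayed close to the reported value. The other 28 are given below. Values without the end runs (the runs of peaks at the ends of 2L, 3L and 4), those for the 100 highest-scoring peaks, those with 1 Mb windows, close neighbours on the main arms alone and the other score tolerances were chosen after seeing the data. The highest-scoring 50% and 25% hold 1069 and 534 peaks by construction, with median scores of 15.13 and 20.35 and median widths of 406 and 513.5 bp. Merging peaks within 500 bp gave a median score of 11.98 and a median width of 338 bp. The means over the list were 14.2 for the score and 386 bp for the width. For 3L, the ratio to expectation was 1.08 in the highest-scoring 25% (adjusted permutation p = 0.51). For 2L, which was not called at 1.08, it turned below 1: 0.98 in the highest-scoring 25% (adjusted permutation p = 0.88) and 0.86 with the 5 main arms alone. Without the end runs, chromosome 4 had a ratio of 1.36, against an expectation that the sparse X, U and Uextra lowered. Among the 100 highest-scoring peaks the ratios were 1.16 for the X, 0.82 for 2L, 1.62 for 2R, 1.08 for 3L, 1.27 for 3R, 0 for chromosome 4 and 1.57 for U. None of these 7 passed the threshold (adjusted permutation p from 0.12 to 0.83), in a list with far fewer peaks. The median score of X peaks exceeded that of peaks on the large autosome arms by 1.89 in the highest-scoring 50% (adjusted permutation p = 0.010) and by 5.395 in the highest-scoring 25% (adjusted permutation p = 0.0011). The share of peaks with a close neighbour exceeded random placement under all 8 alternatives (2 of them chosen after seeing the data), from 31.5% against 8.89% in the highest-scoring 25% to 81.3% against 59.8% within 25 kb. The share of scores that matched was 78.7% within 0.02 and 72.6% within 0.005, with the background fitted anew. Within 0.02 of the background of 50.145 it moved beyond its interval on 2R (76.4%), 3L (78.8%), 3R (81.7%) and the large autosome arms together (79.2%), and within 0.005 on the latter (71.3%). No paired analysis was possible because the list holds no value per replicate, and for the same reason no replicate could be left out. The settings foreseen for annotation, gene lists and motifs were not run, nor was one with another score, since the list holds 1 score per peak. Depth per library is unknown, so its effect on the number of weak peaks was not examined.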

Other observations

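The tests in this part were all chosen after the result was seen. Peaks were unevenly spread within the autosomes as well. The first Mb of 3L held 73 peaks, the most of any 1 Mb window on the main arms. The next windows were the first Mb of 2L, the first Mb of 3R and the window from 5 to 6 Mb on 3R, with 38 peaks each. Windows on the X held between 0 and 17 peaks, with a median of 6, and those on the large autosome arms between 0 and 73, with a median of 19. Beside the loci named above, 14 peaks lay on 3R from 27549004 to 27576043, 13 on 3R from 12060460 to 12099190, and 10 on 2R within 6.50 kb from 4503678 to 4510179. On 2R, 9 peaks from 6305539 to 6325869 had a median score of 26.97. The genome-wide background was matched by all 9 peaks on 3R from 622940 to 632623 and by 3 of the 10 in the 2R locus from 4503678 (exact interval 6.67% to 65.2%).

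No difference was detected in how often strong peaks were part of dense loci. Of the 534 peaks in the highest-scoring 25%, 27.7% lay in loci of 5 or more peaks, against 29.0% of the other 1602 (Fisher's exact test, adjusted p = 0.58 over 2 tests). Single peaks made up 33.5% of these strong peaks and 28.2% of the others (Fisher's exact test, adjusted p = 0.043).

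The lower number of peaks on the X is hard to assign to a few dense autosomal stretches, since the difference held over 115 windows of the main arms (permutation p = 1e-05). Lower X copy number may contribute: unsexed embryos carry fewer X chromosomes than autosome sets, although the labels do not state their sex. If every autosomal pileup that matched the genome-wide background were multiplied by 0.75, 55.0 X peaks would be expected at a pileup of 91 or more, against 310 without that change and 133 observed (95% interval 111 to 158). Among these matched peaks, a factor of 0.75 thus removes more than are missing, and the observed number would need a factor of 0.84. A lower local background on the X is consistent with this, as 92.4% of X peaks matched the genome-wide background and 74.3% of those on the large autosome arms (Fisher's exact test p = 1.0e-07; p = 2.0e-07 when matched within 0.02). The 55.0 lies below the interval of the observed number, but autosomal peaks that did not match were left out of it. Some of them could match on an X with a lower local background, which would raise the 55.0. Whether a uniform factor of 0.75 with otherwise equal peaks is the whole account is therefore undecided. A test at a pileup of 150 or more (X density 0.96 times that of the large autosome arms, 95% interval 0.42 to 1.74, against 0.14 predicted) was set aside: 84 of its 91 peaks are among the 100 highest-scoring, where the near-equal density had been noticed. A different spread of Scute sites between the X and the autosomes stays open and was not tested.

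The runs at sequence ends and on U may reflect sequence present in more copies in the embryos than in the assembly, which would raise the local background along with the ChIP signal. Scores would then match the genome-wide background only by chance, and at other means at most 28.0% of the list did (37.7% within 0.02). For the 21 peaks at the start of 3L and the 11 at the start of 2L the values argue against this as the account of the whole run. On 3L 81.0% matched (exact interval 58.1 to 94.6), and within 0.02 90.5% (69.6 to 98.8). On 2L 81.8% matched (48.2 to 97.7). Of the 17 peaks on U, 64.7% matched (38.3 to 85.8), and within 0.02 70.6% (44.0 to 89.7). Within 0.005 the share on U was 52.9% (27.8 to 77.0), but the highest share at other means was not computed for that tolerance. Within 0.01 and 0.02 the lower bounds on U (38.3 and 44.0) lay above the 28.0% and 37.7% at other means. By that bound the values on U also argue against extra copies as the account of the whole run. The use of the input in peak calling is not given, so how the local background was set is unknown. With a stricter bound of 50%, used first, 2L and U were left undecided. The exact intervals take the peaks of a run as independent, although neighbours may share a local background, so they may be too narrow. Extra copies under part of a run stay open. For the 17 peaks at the high-coordinate end of chromosome 4 the values go with it, since 11.8% matched (1.46 to 36.4; within 0.02, 17.6%, 3.80 to 43.4), against 74.1% in the whole list. The low share in the 2R locus named above lies away from a sequence end, so a low share is not specific to ends. Other explanations, such as the mapping of repeated reads, need a genome of the file's release and were not tested.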
